A study of Homo sapiens with 2 samples.

How the data were processed

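Acetylation of lysine 4 of histone H3 (H3K4ac) was measured by CUT&Tag, in which an antibody directs a transposase to the mark and the fragments it releases are sequenced. The cells were QBC-939, a human cholangiocarcinoma (bile duct cancer) cell line, carrying a scramble short hairpin RNA or a hairpin against WDR5. There were 2 samples, 1 library per group and 0 replicates, so no test between the conditions was possible, and no p-value is given.

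Per the labels' protocols, reads were trimmed with fastp, aligned to hg19 with BWA, and peaks were called with MACS2 and annotated with ChIPseeker, with target genes defined by a peak within 3 kb of a transcription start site (TSS). Versions, the handling of duplicate reads and the counting tool are not given in the sources used here, nor is whether reads or fragments were counted. The authors deposited a single table for both libraries, with 45692 lines that repeat 18221 distinct regions, and each region was used once. The counts in the authors' table are whole numbers per region, without normalization, and the lowest is 1. The deposited RPM values equal the count plus a pseudocount of 1 read, divided by a single total per library, as found from the values (largest difference 0.000443%). One read was worth 0.0552 RPM in the scramble library and 0.0556 RPM in the shWDR5 library, which gives totals of 18129079 and 17979144. The deposited fold enrichment is a ratio of RPM density to that of a uniform genome, not to a control library, and was not used further. The log2 ratios used here were computed from the RPM columns and differ from the authors' log2 column by at most 5.0e-10. The authors' marks of the library in which a region was called were used as deposited.

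The columns of the table are named for a control and for a second library whose name is not explained in the sources used here. The control columns were taken as scramble, the only control in the labels, and the others as shWDR5, the only other sample. The deposited comparison is named sh against scr, and its log2 ratio is that of the second library over the control, which goes with this assignment. Were the columns exchanged, every direction given here would turn.

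Region coordinates are those of the table, on hg19. They were checked against GRCh37, where 0 regions ran past a chromosome end, and of 16895 regions whose transcript was found in GENCODE 44 lifted to GRCh37, 80.8% had the same transcript start and end. Nearest genes and TSS distances are those of the table, which refer to any annotated transcript. Gene features around named regions came from GENCODE. The names of 6 genes had been turned into dates and were restored through their gene identifiers. No name was given in the table for the nearest gene of 9595 regions. GC content came from the reference sequence.

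For every region the ratio of shWDR5 to scramble was computed from raw counts over library totals, with exact binomial (Clopper-Pearson) 95% intervals. Intervals of medians were binomial, from order statistics over regions. Intervals of differences and ratios of medians, and of the GC-stratified difference of means, came from resampling regions. The intervals of single regions cover counting error only. The other intervals treat regions as independent draws, although all come from the same 2 libraries. All intervals leave out the variation between cultures and do not allow for the choice of regions by their value. Since PCR copies are not independent molecules, the intervals also leave out part of the technical variation. Ratios past a 2-fold limit were counted. A gene was represented by its region within 3 kb of the TSS with the highest mean RPM. For gene lists with at least 3 such genes, the median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 10 bins. Shares of regions near the 5' end of a protein-coding gene were set against 252604 random positions, unmatched or matched on GC content in bins of 4%.

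The lists and the rule for named genes were fixed before the data were examined. Named genes were WDR5 and HDAC2, the 10 genes at each end by log2 ratio among those with a promoter region above the median of mean signal (without LOC, antisense, LINC, MIR, SNOR and RNU names), the 2 highest and 2 lowest members of each list, and the 3 regions at each extreme above that median. Some genes that this rule takes from the lists are not reported here. The 20 lists covered WDR5 and H3K4 methyltransferase complexes, histone deacetylases and corepressors, histone acetyltransferases, epithelial-mesenchymal transition, hypoxia, biliary, hepatocyte, fibroblast, immune and endothelial markers, ribosomal protein genes, cell cycle, p53 and apoptosis, MYC targets, interferon, immediate early genes, developmental signalling, cholangiocarcinoma tumour suppressors, HOX genes and housekeeping genes.

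The procedure was tested on simulated counts for the same 18221 regions. The 2-fold limit was passed by 96.0% of regions simulated at 4-fold higher, by 48.0% at 2-fold higher and by 42.0% at 2-fold lower, and by 5.35% of 18021 regions simulated without a difference. A true 2-fold difference lies at the limit itself, so its share says little about depth. The intervals held the simulated fold in 96.2% of 1822 regions checked. The simulated counts carried counting error only, without the choice of regions by calls and without PCR copies. These shares are therefore no baseline for the regions observed past the limit. Of random lists of 8 genes among 3488 genes, 5.0% fell outside the middle 95%, and 74.0% of lists shifted by 1 on the log2 scale were found.

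Alternatives varied the fold limit, centring, pseudocount, scaling (TMM factors from edgeR 4.0.16 in R 4.3.3, median of ratios), the set of regions, the promoter distance, the region standing for a gene and the matching of lists. Planned thresholds on an authors' p or q were not run, since the columns used here hold neither. Alternatives added after seeing the data were scaling to the total over regions and to mitochondrial counts, regions called in both libraries, regions with at least 100 counts, chromosomes 1 to 22 and X alone, removal of an over-represented region width, and GENCODE promoters. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.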

Results

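H3K4ac was profiled by CUT&Tag in QBC-939 human cholangiocarcinoma cells that carried a scramble hairpin or a hairpin against WDR5, a WD-repeat subunit of H3K4 methyltransferase complexes. There was 1 library per group and no replicate, so all values below describe these 2 libraries. The scramble library had a total of 18129079 counts and the shWDR5 library 17979144. The assignment of the table's columns to the groups rests on the word control and on the name of the comparison, sh against scr. Every direction would turn if the columns were exchanged. The 18221 regions had a median width of 240 bp (interquartile range 200 to 334 bp). They held 5.86% of the scramble library (1062721 counts) and 4.99% of the shWDR5 library (897831 counts). Of these counts, 44.3% and 43.8% lay in 10 mitochondrial regions. The median region held 19 counts in scramble and 15 in shWDR5, so that single regions are imprecise.

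WDR5 was the nearest gene of 0 regions, and its knockdown could not be checked from these data. HDAC2, a histone deacetylase that the series title names as a partner of WDR5, had a promoter region (chromosome 6, 114292362 to 114292642) that held 17 counts in scramble and 20 in shWDR5. The ratio was 1.19 (95% interval 0.590 to 2.41), and no difference was detectable at this depth.

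The design asks how H3K4 acetylation differs between the scramble and shWDR5 cells. Peaks were called in 13247 regions in the scramble library and in 7701 in the shWDR5 library. Of all regions, 10520 were called in scramble only, 4974 in shWDR5 only and 2727 in both. At the authors' scaling, 5245 regions were at least 2-fold lower in the shWDR5 library and 2261 at least 2-fold higher, so that 69.9% of the regions past the limit were lower. The counting interval excluded 1 for 4360 of the lower and 1799 of the higher regions. Of the lower regions 5180 were called in scramble only, and of the higher regions 2226 in shWDR5 only. Regions chosen by a call in the library where they are high, and by a 2-fold limit, tend to exclude 1 by that choice. The interval counts are therefore no support for a difference. The split between lower and higher regions depended on the scaling, which no spike-in fixes here. With TMM factors 42.5% of the regions past the limit were lower, with median of ratios 40.1%, after centring on the median 41.7%, and with scaling to the total over regions 57.3%. Of that total, 44.3% in scramble and 43.8% in shWDR5 was mitochondrial, and scaling to mitochondrial counts gave a like share, 56.4%.

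The median log2 ratio over all regions was -0.47 (95% interval -0.49 to -0.45), with quartiles at -1.14 and 0.36. It lay at -0.99 for regions called in scramble only and at 0.90 for regions called in shWDR5 only, classes that are set by the counts themselves. Regions called in both libraries had a median of -0.08 (-0.09 to -0.06), and 96.5% of them lay within 2-fold. The median was lowest at low depth. It was -1.09 for regions with up to 20 counts over both libraries, -0.63 from 20 to 40 counts and -0.03 (-0.07 to 0.01) from 100 to 200 counts. Above that it was -0.09 (-0.15 to -0.07) from 200 to 1000 counts and -0.11 (-0.19 to -0.03) beyond. TMM factors moved the median over all regions by 0.45 and median of ratios by 0.49, to -0.02 and 0.02.

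**Figure D1:**
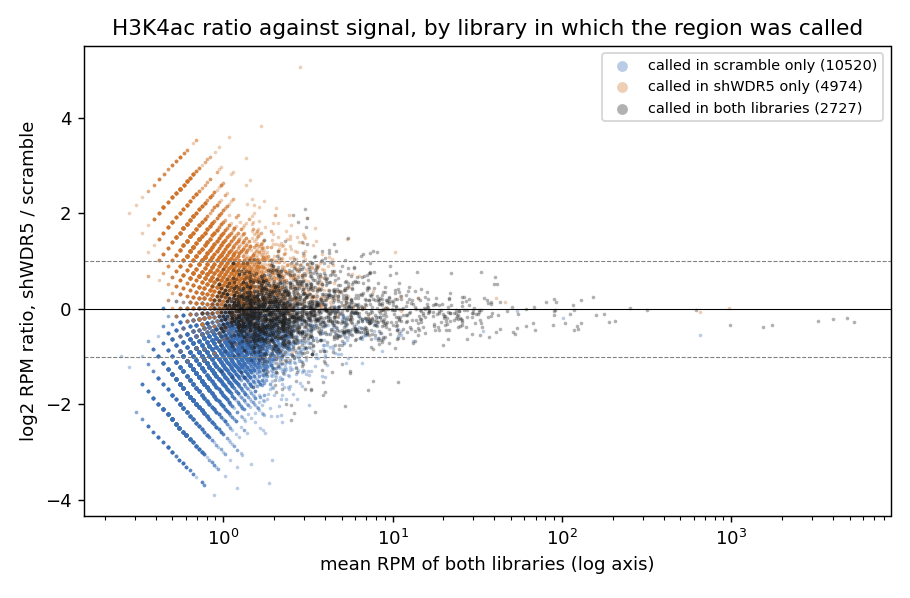
Each point is a region, placed by its mean RPM over both libraries (log axis) and its log2 RPM ratio of shWDR5 to scramble, coloured by the library in which it was called, with dashed lines at 2-fold. The 2727 regions called in both libraries centre on a log2 ratio of -0.08, and the wide spread lies at low signal.

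The regions were spread unevenly over the chromosomes in both libraries. The short arm of chromosome 18 held 21.4 regions per Mb, against 2.90 on its long arm and a median of 6.78 over 41 arms.

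**Figure D2:**
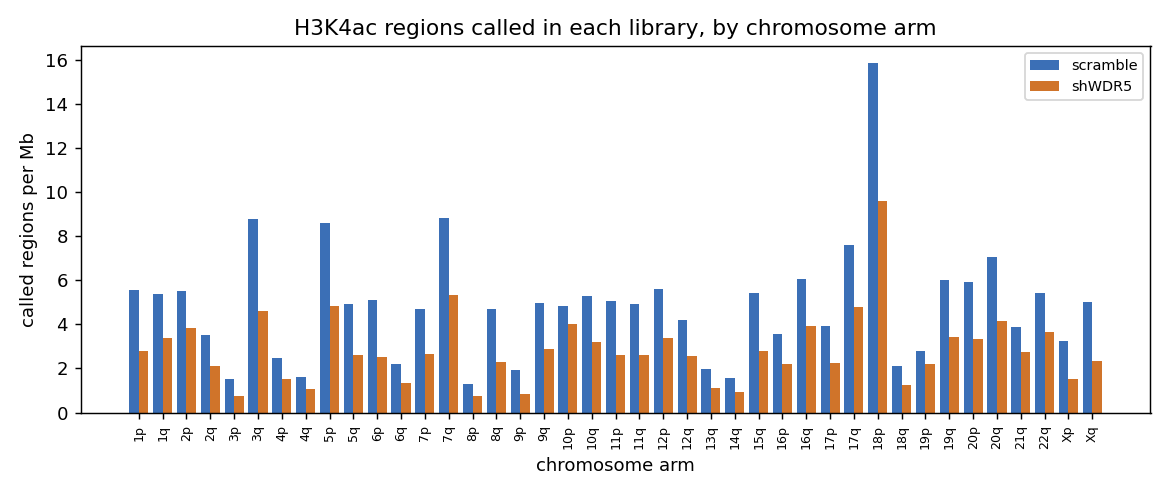
Bars give the number of regions called in the scramble and in the shWDR5 library per Mb of reference sequence, for each of 41 chromosome arms. The arm 18p has the tallest bars in both, 15.8 per Mb in scramble and 9.61 in shWDR5.

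The ratio of scramble-only to shWDR5-only calls was highest at promoters. Among regions that overlapped a TSS, 1309 were called in scramble only and 318 in shWDR5 only, a ratio of 4.12 (95% interval 3.64 to 4.67). The ratio was 2.60 (2.35 to 2.88) up to 1 kb from a TSS, and 1.81 (1.60 to 2.04) from 1 to 3 kb. Beyond 50 kb it was 1.99 (1.83 to 2.15). The ratio also rose with GC content, from 1.13 at 40 to 50% GC to 4.02 at 70 to 80%. Within GC bins the odds ratio of scramble-only calls near protein-coding 5' ends was 1.43, against 1.90 without bins. For regions with at least 100 counts, the side that lay nearer 0 depended on the scaling. The median log2 ratio was -0.23 within 3 kb of a TSS and 0.026 away from it at the authors' scaling, 0.00039 and 0.26 scaled to the total over regions, and 0.22 and 0.48 with TMM factors. Regions within 3 kb of a TSS made up 31.5% (30.2% to 32.8%) of the regions at least 2-fold lower in shWDR5 and 22.4% (20.7% to 24.2%) of those at least 2-fold higher. Over all regions this share was 30.7%, which lay inside the interval of the lower regions. At this distance and limit, only the higher regions departed from it. At a 1.5-fold limit the share of lower regions was 32.5%. Near the 5' end of protein-coding genes in GENCODE lay 15.7% of all regions, against 3.89% of random positions and 12.4% of random positions of the same GC content. Against positions of the same GC content, regions called in both libraries were near such a 5' end 1.49 times as often (1.37 to 1.61) and scramble-only regions 1.33 times as often (1.28 to 1.39). For shWDR5-only regions the ratio was 0.969 (0.889 to 1.05).

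**Figure D3:**
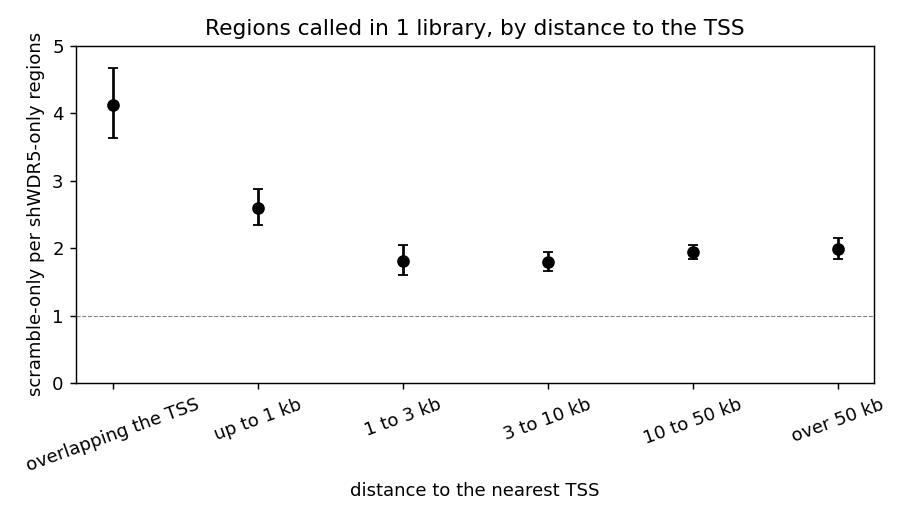
The number of regions called in scramble only per region called in shWDR5 only is plotted for 6 classes of distance to the nearest TSS, with exact binomial 95% intervals and a dashed line at 1. The ratio is 4.12 at the TSS and between 1.80 and 1.99 in the classes beyond 1 kb. The classes are not matched on GC content.

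A promoter region was found for 5084 genes, of which 1501 were at least 2-fold lower in the shWDR5 library and 453 at least 2-fold higher. With TMM factors, genes with promoter regions numbered 764 lower and 789 higher. Among the 287 genes whose region held at least 100 counts, 19 were lower and 9 higher, with a median log2 ratio of -0.23 (-0.27 to -0.18) at the authors' scaling. Scaled to the total over regions this median was 0.00105 (-0.04 to 0.05), and with TMM factors it was 0.22 (0.18 to 0.27).

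Promoter regions were assigned by the nearest transcript of any kind. For 25 of the 64 named genes found in GENCODE the outermost 5' end of the gene record was not within 3 kb of the region. They were HDAC2, ZNF516, EPB41L1, HEATR2, SLITRK6, RAB5C, SLC12A9, APOBEC3A, TTLL5 and IGFBP3, and, in the lists, KMT2D, MTA3, CHD3, CDH1, CLDN4, PCNA, PLK1, CASP8, TERT, CDK4, OAS2, CTNNB1, EGFR, AXIN2 and RAB7A. A gene can have further transcript starts inside its record. The regions of HDAC2, SLC12A9, TTLL5, PCNA and CDK4 overlapped the assigned TSS, so the distance to the outermost end does not show that they lie outside promoters.

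The highest ratio belonged to a region of 201 bp near EGLN1, an oxygen sensor that hydroxylates hypoxia-inducible factors (chromosome 1, 231559277 to 231559477, 1313 bp from the TSS). It held 2 counts in scramble and 98 in shWDR5, a ratio of 49.4 (13.3 to 414). ZNF516 followed with 4 and 35 counts and a ratio of 8.82 (3.15 to 34.2), and AC017028.1, within an intron of HDAC4, with 6 and 31 counts. COX20, an assembly factor of cytochrome c oxidase, had 6 and 28 counts at its TSS, a ratio of 4.71 (1.91 to 13.9). MKI67, the gene of the proliferation marker Ki-67, had 7 and 27 counts in an intron 1429 bp from the TSS, a ratio of 3.89 (1.65 to 10.6). HSP90AB1, a cytosolic chaperone, had 9 and 31 counts. EPB41L1, FBXL7, VWA7 and HEATR2 had log2 ratios of 1.97, 1.77, 1.76 and 1.70.

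The lowest ratio belonged to an intronic region of 222 bp in SLITRK6 (chromosome 13, 86373884 to 86374105), with 40 counts in scramble and 2 in shWDR5, 19.8 times as many in scramble (5.14 to 169). RAB5C, a GTPase of early endosomes, had 40 and 4 counts in an intronic region of 218 bp, and IGFBP3, which binds insulin-like growth factors, had 67 and 12 counts in an exonic region of 221 bp (chromosome 7, 45953848 to 45954068). Among widths above 200 and up to 300 bp, regions of 218 to 221 bp were over-represented. Their median log2 ratio was -0.95, which bears on RAB5C and IGFBP3, on the B4GALNT3 region given below and, in the lists, on CHD3 and CTNNB1. The SLITRK6 region was 1 bp wider. SOX2, a pluripotency and progenitor transcription factor, had 38 counts in scramble and 4 in shWDR5 over its coding exon (chromosome 3, 181430684 to 181431070), 9.42 times as many in scramble (3.39 to 36.3). METTL3, the catalytic subunit of the RNA m6A methyltransferase, had 32 and 4 counts at its TSS, 7.93 times as many in scramble (2.81 to 30.9). SLC12A9, HAUS3, APOBEC3A, EAF2 and TTLL5 had log2 ratios of -2.88, -2.54, -2.49, -2.40 and -2.40. All 20 genes at both ends were called in 1 library only.

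**Figure D4:**
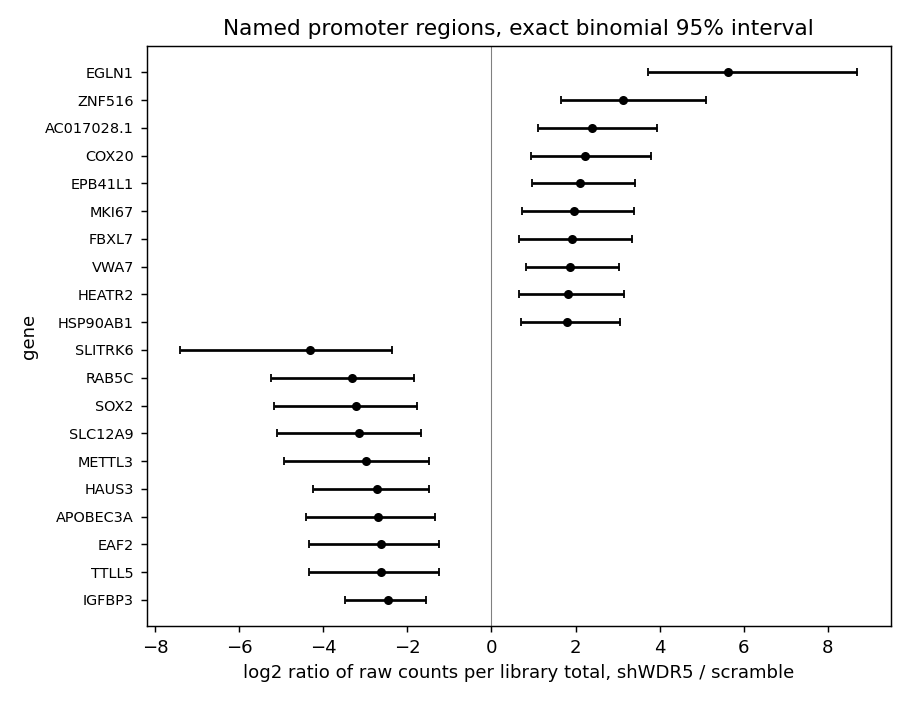
Log2 ratios of raw counts per library total, shWDR5 over scramble, are plotted for the 20 genes at both ends, with exact binomial 95% intervals for counting error. EGLN1 lies highest, at 98 counts against 2, and SLITRK6 lowest, at 2 counts against 40.

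Of the 3 regions at the upper extreme, EGLN1 was one, and the others were intergenic, at chromosome 7, 63212559 to 63212886 (3 and 55 counts, ratio 18.5, 6.00 to 92.4) and at chromosome 12, 87880154 to 87880444 (2 and 35 counts, ratio 17.6, 4.53 to 151). At the lower extreme, beside SLITRK6, lay an intronic region of 218 bp in B4GALNT3 on chromosome 12, 616125 to 616342, with 62 and 4 counts, and an intronic region of CLYBL on chromosome 13, 100382241 to 100382685, with 33 and 2 counts.

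Among WDR5 and its H3K4 methyltransferase complexes, 4 of 18 genes had a promoter region, with a median log2 ratio of -1.48 at percentile 6.17 of random lists. KMT2D held 28 and 4 counts (-2.52) and ASH2L 23 and 4 counts (-2.25), while the intervals of KMT2A (-0.70) and KDM6A (-0.23) included no difference. The KMT2D region overlapped a coding exon over 2 kb from the assigned TSS, and within 1 kb, where it drops out, the median of the list was -0.70. Histone deacetylases and corepressors had 10 of 34 genes, with a median log2 ratio of -1.004 at percentile 8.62. MTA3 (-1.93) and CHD3 (-1.65), subunits of the NuRD complex, lay lowest, and the CHD3 region was 221 bp wide. The 3 histone acetyltransferases had a median of 0.33 at percentile 91.7, with EP300 at 1.12 (12 and 27 counts), KAT6B at 0.33 and KAT5 at -0.91.

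The immune cell markers were the only list outside the middle 95% of random lists, with 3 of 15 genes, a median of 0.96 and percentile 98.1. Of the 12 lists with a percentile, 0.6 would lie outside by chance. CD8A held 12 and 27 counts (1.12), GNLY 12 and 24 (0.96) and CD14 17 and 9 (-0.84). On chromosomes 1 to 22 and X alone this list, like all others, lay within the middle 95%. Among other cell types, hepatocyte, fibroblast and endothelial markers had 0 genes with a promoter region. Of the biliary markers, CLDN4 had a log2 ratio of 0.96.

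Hypoxia genes had a median of -0.43 over 9 genes (percentile 70.0), between EGLN1 and LDHA (-1.62), with CA9 at -0.99 and ANKRD37 at 0.67. MYC and its targets had a median of -0.72 over 8 genes (percentile 9), with TERT at -1.31, NPM1 at 0.01 and CDK4 at 0.43. The p53 and apoptosis list had a median of -0.90 over 6 genes (percentile 12.3), with CDKN2B at -1.50, GADD45A at 0.57 and CASP8 at 0.62. CASP8 turned to -0.921 with the region nearest the TSS. Cell cycle genes had a median of -0.52 over 10 genes (percentile 66.7), with E2F3 at -1.11, PCNA at -0.82, PLK1 at 1.20 and MKI67 at 1.82. The PLK1 region lay in a coding exon of ERN2, 2384 bp from the assigned TSS, and its ratio of 2.52 had an interval that included 1 (0.924 to 7.93). Developmental signalling genes had a median of -0.71 over 9 genes (percentile 36.4), with CTNNB1 at -2.65, EGFR at -2.42, AXIN2 at 0.05 and LGR5, a stem cell receptor, at 1.82. The CTNNB1 region was 219 bp wide.

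Cholangiocarcinoma tumour suppressors had a median of -0.82 over 5 genes (percentile 21.5), with NF2 at -0.88 and RNF43 at 0.67. This median turned to 0.675 within 1 kb. With means over promoter regions it turned to 0.300, as did NF2. Ribosomal protein genes had a median of -0.44 over 10 genes (percentile 71.8), with RPL26 at -1.52, RPS24 at -1.31, RPL5 at 0.23 and RPL7 at 0.91. Housekeeping genes had a median of -0.26 over 6 genes (percentile 77.3), with RAB7A at -1.86, C1orf43 at -0.60, SDHA at 0.62 and TUBA1B at 0.70. SDHA turned to -0.414 with means over promoter regions. The medians of the hypoxia, ribosomal and housekeeping lists turned above 0 with TMM factors and median of ratios, which raised all genes alike. Of lists with fewer than 3 genes, epithelial-mesenchymal transition had THBS1 (-1.75) and CDH1 (1.14), interferon genes had RELB (-0.07) and OAS2 (1.01), and immediate early genes had JUN (-0.43). HOX genes had 0 regions.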

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

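Scaling to the total over regions or to mitochondrial counts, rescaled counts and medians of genes, the sets of regions called in both libraries, with at least 100 counts or on chromosomes 1 to 22 and X, GENCODE promoters and removal of the fixed width were chosen after seeing the data. The cause of the changes was not tested, except where a limit, a centring or a smaller set changes a count by construction. Regions higher and lower numbered 3692 and 8277 at a 1.5-fold limit, 439 and 1116 at 4-fold, 1493 and 3475 with pseudocount 5, and 636 and 1467 above the median signal. Centred on the median, they numbered 3913 and 2795, with TMM factors 3829 and 2834, and with median of ratios 3980 and 2666, so that the majority turned. Regions called in both libraries gave 33 and 63, and those with at least 100 counts 40 and 46. The median log2 ratio over regions (-0.47 as reported) was -0.547 for promoter regions, -0.264 above the median signal, -0.403 weighted by width and -0.403 with pseudocount 5, -0.491 with pseudocount 0.2, -0.242 scaled to the total over regions, -0.226 scaled to mitochondrial counts, -0.075 for regions called in both libraries and -0.067 with at least 100 counts. It was -0.0199 with TMM factors and reversed to 0.0215 with median of ratios. The share near a TSS stayed higher among lower than among higher regions in each alternative run. Within 1 kb it was 24.7% and 14.1%, where 11.5% of all regions overlapped a TSS and 11.7% lay up to 1 kb away. With GENCODE promoters it was 16.5% and 7.95%, against 15.7% of all regions. After centring it was 29.4% of lower regions, against 30.7% of all regions within 3 kb. Genes with higher promoter regions numbered 293 within 1 kb and 281 with pseudocount 5. Higher and lower genes numbered 789 and 764 with TMM factors, 830 and 717 with median of ratios, 7 and 25 among regions called in both libraries, and 9 and 19 with at least 100 counts. Of the gene lists, 2 lay outside the middle 95% within 1 kb, and 0 with the region nearest the TSS, with regions called in both libraries or on chromosomes 1 to 22 and X. With TMM factors and median of ratios, median log2 ratios turned to 0.0250 and 0.0664 for hypoxia, 0.0169 and 0.0582 for ribosomal proteins and 0.194 and 0.236 for housekeeping genes, and those of KDM6A to 0.225 and 0.266, RELB to 0.383 and 0.424 and JUN to 0.0250 and 0.0664. Scaled to the total over regions and to mitochondrial counts, KDM6A turned to 0.00224 and 0.0189 and RELB to 0.161 and 0.177. The tumour suppressor list turned to 0.675 within 1 kb and 0.300 with means over promoter regions, where CASP8 was -0.149, NF2 0.3005 and SDHA -0.414. CASP8 was -0.921 with the region nearest the TSS. The list of WDR5 and its H3K4 methyltransferase complexes (-1.48 as reported) was -0.704 within 1 kb. The MYC list was 0.0120 for regions called in both libraries. Of the values of named genes and list medians that did not turn, 962 stayed within their counting interval or their members' range, and 4 moved past it in the same direction. Part of the 962 could not change. The matching of lists alters only the random lists, and a smaller set of regions leaves the ratio of a kept region as it was. Planned p or q thresholds were not run. Of regions simulated without a difference, 5.35% passed the 2-fold limit, and 2.21% of those above the median signal. The simulation left out the choice of regions by calls, so these shares are no baseline for the observed counts. No paired analysis was possible because each group had 1 library.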

Other observations

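All tests in this part were chosen after the data had been examined. Beyond chromosome 18, the density of regions differed between other arms of one chromosome. The arm 3q held 11.9 and 3p 2.14, 5p 11.8 and 5q 6.78, and 8q 6.13 and 8p 1.67. Within arms, the densest window of 1 Mb, on chromosome 17 from 36 to 37 Mb, held 88 regions, and the next, on chromosome 22 from 19 to 20 Mb, held 55, against a median of 6 per window with a region.

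Gene density as the whole source of this unevenness is argued against, since regions over 3 kb from a TSS were 6.90 times as dense on 18p as on 18q (95% interval 5.55 to 8.61), where protein-coding genes were 1.27 times as dense. A candidate explanation is copy number. Promoter regions called in both libraries had a median of 43.5 scramble counts on the 11 densest arms and 31 on the 11 sparsest. The ratio was 1.40 (1.17 to 1.59), with an interval over regions and not over arms. Arms were ranked by called regions, and calls depend on counts, so a ratio above 1 does not decide on copy number. Copy number was not measured here and stays open, as does a mark that truly differs between arms.

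More regions lower than higher in shWDR5 may have several sources. Calling of weak regions in 1 library stays open, near the TSS and away from it. Regions with at least 100 counts had a median log2 ratio of 0.026 (-0.01 to 0.07) away from the TSS and -0.23 (-0.28 to -0.18) near it at the authors' scaling, but 0.26 and 0.00039 when scaled to the total over regions. The difference between both medians, -0.26 (-0.32 to -0.20), is free of scaling. GC content goes with a large part of the calls, since scramble-only regions per shWDR5-only region numbered 1.13 at 40 to 50% GC and 4.02 at 70 to 80%. As the whole source of the excess of scramble-only calls near protein-coding 5' ends, GC content of the region itself is argued against. The odds ratio of that excess was 1.43 (1.27 to 1.62) within GC bins, against 1.90 without them. GC content of the surrounding sequence and depth were not matched, and the odds ratio does not decide for regions elsewhere. For regions with at least 100 counts, the difference of means between promoters and other regions was -0.25 before and -0.090 (-0.19 to 0.01) after GC stratification, which leaves GC open there.

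Lower enrichment over background in the shWDR5 library cannot be told apart from a lower mark, since each group had 1 library. The share of the library in chromosome regions was 0.856 times that of scramble. The mitochondrial share was lower by a like factor, 0.842. Mitochondrial DNA carries no histones, so this value does not measure the mark. With 1 library per group it does not decide between both sources. An exchange of the 2 columns cannot be excluded from the counts either, as regions whose nearest gene is WDR5 numbered 0. The name of the comparison, sh against scr, goes with the assignment used. The series title states that WDR5 promotes histone deacetylation, which with this assignment runs against the lower counts at promoters at the authors' scaling, so the assignment deserves a check with the authors. An effect of the knockdown itself stays open and untested.

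Regions of one fixed width, 218 to 221 bp, numbered 104 per bp of width against 73.8 among widths up to 10 bp away. This width was searched above 200 and up to 300 bp, among regions called in both libraries. The lowest width, 200 bp, was more frequent, with 6177 regions, and lay outside the search. Regions of 218 to 221 bp made up 19.3% (13.1% to 26.8%) of the regions at least 4-fold lower in shWDR5 and above the median signal. They made up 2.37% of the other regions above that median. Reads that share an end at one position may explain them, since 64.9% (60.1% to 69.5%) had a summit within 10 bp of the centre, against 47.9% of neighbouring widths. GC content is argued against under this definition, as regions under 45% GC had a median log2 ratio lower by -1.06 (-1.47 to -0.65) than neighbouring widths. The width was defined in 3 ways after the pattern was seen, and the answer on GC is not the same in all. A range drawn by eye, up to 222 bp, gave -1.40 (-1.84 to -1.01). The most frequent width of the search alone, 218 bp, gave -0.45 (-0.95 to -0.01), which does not decide. Its neighbours include the other over-represented widths. No biological explanation was tested.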
